A study of Mus musculus with 12 samples.

How the data were processed

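RNA sequencing was analysed for 12 libraries of bone marrow-derived macrophages from male Ldlr-knockout mice, 3 in each of 4 groups (WT or S196A, basal or ligand). Per the labels, messenger RNA was selected by its poly(A) tail and prepared with a stranded kit and 12 cycles of PCR. The authors deposited 1 table of read counts per library, which lists whole-number counts for 24421 genes by symbol and 2 summary lines for reads in no gene and in more than 1 gene. Per the submitters' processing notes, bcl2fastq 2.17, STAR 2.5.0b, DESeq2 and the mm10 genome were used, and the counting program, the gene annotation and the strand setting are not given in the sources used here. Counts of antisense and overlapping genes are therefore uncertain, and so are counts of near-identical copies such as Lyz1 and Lyz2, the Bcl2a1 family, Hspa1a and Hspa1b, and the H2 genes. Reads outside genes made up 13.6% to 16.9% of the reads listed per library and ambiguous reads 0.616% to 0.753%, and both were left out. Reads in genes ranged from 10704620 to 16193578 per library, genes with a read from 13486 to 14483, and the 10 most counted genes took 8.31% to 9.83% of the reads.

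Groups and replicate numbers were taken from the labels. WT libraries carry library numbers 1 to 6, and S196A libraries carry 7, 8 and 10 to 13. A batch that followed this order could not be told apart from genotype. S196A basal 3 carries library number 13, where 9 would be next in the order, and the labels do not say why. The origin of the replicates is not stated, so it is not known whether the 3 libraries of a group come from 3 mice or 3 cultures, and a p-value measures the spread between libraries, which may be technical. Within groups the counts differed by more than counting error (chi-square per degree of freedom 2.66 to 17.5), so no 2 libraries of a group differed by counting error alone. Repeat preparations of 1 sample are not excluded by this.

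Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered by filterByExpr with the group as factor (11535 kept) and scaled by TMM, with factors of 0.960 to 1.000 in WT and 1.010 to 1.048 in S196A. One quasi-likelihood model with a mean per group was fitted over all 12 libraries. From it came 5 comparisons: S196A against WT without and with ligand, ligand against no ligand in WT and in S196A, and the difference of both ligand responses. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Fold changes are on the log2 scale with a standard error (SE) equal to the fold change divided by the root of the test's F, and 95% intervals use the moderated degrees of freedom. CPM values are TMM-normalised. A floor of 3 reads per library is given in CPM and covers counting error only.

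Before the data were examined, 31 gene lists, the comparisons, the tests and the rule for naming genes were fixed. The lists were LXR targets, sterol synthesis, fatty acid synthesis, mitosis, DNA replication, p53 targets, inflammatory genes, interferon-stimulated genes, phagocytosis and efferocytosis, alternative activation, pro-apoptotic genes, anti-apoptotic genes, glycolysis and hypoxia, unfolded protein and integrated stress response, lysosome, MHC class II, macrophage markers, monocyte markers, neutrophil and granulocyte precursor markers, dendritic cell markers, B cell markers, T and NK cell markers, erythroid markers, mast cell and basophil markers, megakaryocyte markers, osteoclast markers, stromal and fibroblast markers, endothelial markers, immediate early genes, heat shock genes and mitochondrially encoded genes. A list with at least 5 tested members was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. Members were also counted after adjustment over the list alone. Epb42 was matched under its older symbol.

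Genes named are of 4 kinds. Nr1h3, Nr1h2, Ldlr, Lyz2, Foxm1, Mki67, Abca1, Abcg1, Srebf1 and Apoe are always named. For each comparison of 2 groups, the 10 largest log2 fold changes each way are named among genes that passed, had a mean log2 CPM of at least 1, showed no overlap between the libraries of both groups and did not carry a predicted-gene name. The same rule without the overlap condition applies to the difference of ligand responses. The 4 members of each list with the smallest p are named as well. F630028O10Rik lies outside the rule by its name and was chosen after its values were seen, and the same holds for Lyz1, Xist and Ddx3y. Positions are from the mm10 (GRCm38) annotation and were found for 11095 of 11535 tested genes (96.2%).

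The pipeline was tested on simulated counts with 200 changed genes. At 1.5-fold, 2-fold and 4-fold it recovered 68.7%, 85.1% and 97.0% for the genotypes without ligand (2.34% of calls false, 11455 genes), 70.1%, 86.6% and 97.0% with ligand (2.31%, 11453 genes), 62.7%, 83.6% and 95.5% for ligand in WT (4.73%, 11445 genes), 73.1%, 80.6% and 95.5% for ligand in S196A (4.05%, 11457 genes), and 34.3%, 71.6% and 90.9% for the difference (7.09%, 11442 genes). With the mitosis list raised, that list was called and 0 others among the 24 lists tested. Each simulated gene varied independently, so this does not test the effect of correlation within lists. The simulated libraries also held no state shared across genes, so these shares of recovered and false calls may not hold in the data. In the data the correlation within lists was estimated at 0.325 for mitosis and 0.937 for interferon-stimulated genes.

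Alternatives were size factors of DESeq2 1.42.0, library totals without a composition factor, no filter, a filter of 1 CPM in 3 samples, the DESeq2 test, limma voom, a replicate block, fits of the 2 groups alone, and each library left out in turn. Chosen after seeing the data were fits with 2 libraries left out together and with the level of interferon-stimulated genes as a covariate. In each table of calls a count is taken as moved when it differs by more than 1.5 times. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.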

Results

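Messenger RNA was sequenced from macrophages grown from the bone marrow of male mice that lacked Ldlr, the gene of the low-density lipoprotein receptor. The mice were 20 weeks old and had eaten a Western diet for 12 weeks. The cells carried either wild-type LXRα (WT), a nuclear receptor that senses oxidised cholesterol, or LXRα with the S196A change that disrupts its phosphorylation (S196A). They were kept without ligand (basal) or with a ligand that the labels do not name. Each of the 4 groups held 3 libraries, named here by group and replicate number. Reads assigned to genes numbered 15293626, 15022989 and 15279255 in WT basal 1 to 3 and 10704620, 13639591 and 14882996 in WT ligand 1 to 3. S196A basal 1 to 3 held 15427519, 15337733 and 13697231 reads, and S196A ligand 1 to 3 held 15357742, 14054373 and 16193578. Of 24421 genes, 7749 had no read in any library and 11535 were tested. Levels are TMM-normalised CPM, given as mean ± SD with n = 3, and 3 reads corresponded to 0.185 to 0.280 CPM.

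Nr1h3 (chromosome 2, 91184061 to 91202834, mm10), which encodes LXRα, was detected in every library with 102 to 201 reads. Its level was 12.8 ± 0.979 CPM in WT basal, 10.5 ± 1.19 in WT ligand, 11.2 ± 0.377 in S196A basal and 9.39 ± 0.173 in S196A ligand. Nr1h3 did not pass between the genotypes, with log2 fold changes of −0.18 without ligand (adjusted p = 0.242) and −0.17 with ligand (adjusted p = 0.274). Its mean was lower in S196A in both states, so a small fall is not excluded. A change of a single amino acid leaves no mark on a gene's read count, so these values do not check the genotype labels. Nr1h2, which encodes the sister receptor LXRβ, stood at 89.5 ± 2.93 CPM in WT basal and 92.1 ± 7.52 in S196A basal. Ldlr (chromosome 9, 21723483 to 21749919) was read at 426 ± 18.1 CPM in WT basal, 553 ± 4.94 in WT ligand, 453 ± 56.0 in S196A basal and 510 ± 24.6 in S196A ligand. Counts per gene do not show which part of the Ldlr transcript was present, so they do not check the knockout either.

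The first comparison asked how S196A macrophages differed from WT macrophages without added ligand. Genes of cell division stood far higher in S196A. Mki67 (chromosome 7, 135689784 to 135716361), whose protein marks dividing cells, was at 58.8 ± 13.9 CPM in S196A against 9.53 ± 2.32 in WT (6.16-fold, log2 2.62, SE 0.213, adjusted p = 1.09e-05). Foxm1 (chromosome 6, 128362967 to 128376146), a transcription factor that switches on mitotic genes, was 4.45-fold higher at 9.44 against 2.11 CPM (adjusted p = 4.14e-05). Cenpf (chromosome 1, 189640606 to 189688086), a kinetochore gene, rose 11.1-fold from 0.716 to 8.07 CPM (SE 0.301, adjusted p = 1.41e-05). Ube2c rose 10.9-fold, the nucleotide-synthesis gene Rrm2 9.51-fold and the cyclin gene Ccna2 from 0.962 to 9.75 CPM. The 10 largest rises under the naming rule, which also held Aspm, Ccne2, Casc5, Anln, Ccnb2 and Nusap1, were genes of mitosis or DNA synthesis. Of 29 tested genes in the mitosis list, 27 were higher, 0 lower and 2 not passed, and 28 were higher when adjusted over the list alone. The list's median log2 fold change was 2.15, its camera adjusted p was 3.46e-30, and the adjusted p = 0.074 with an estimated correlation. Genes of DNA replication followed, with 22 of 33 higher, 0 lower and 11 not passed, and 27 higher adjusted over the list alone. Their median was 0.61 (camera adjusted p = 6.62e-14; adjusted p = 0.316 with an estimated correlation), and Chaf1a, a chromatin assembly gene, rose by 1.15 on the log2 scale. With 1 library left out, between 26 and 28 mitosis genes were higher.

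**Figure D1:**
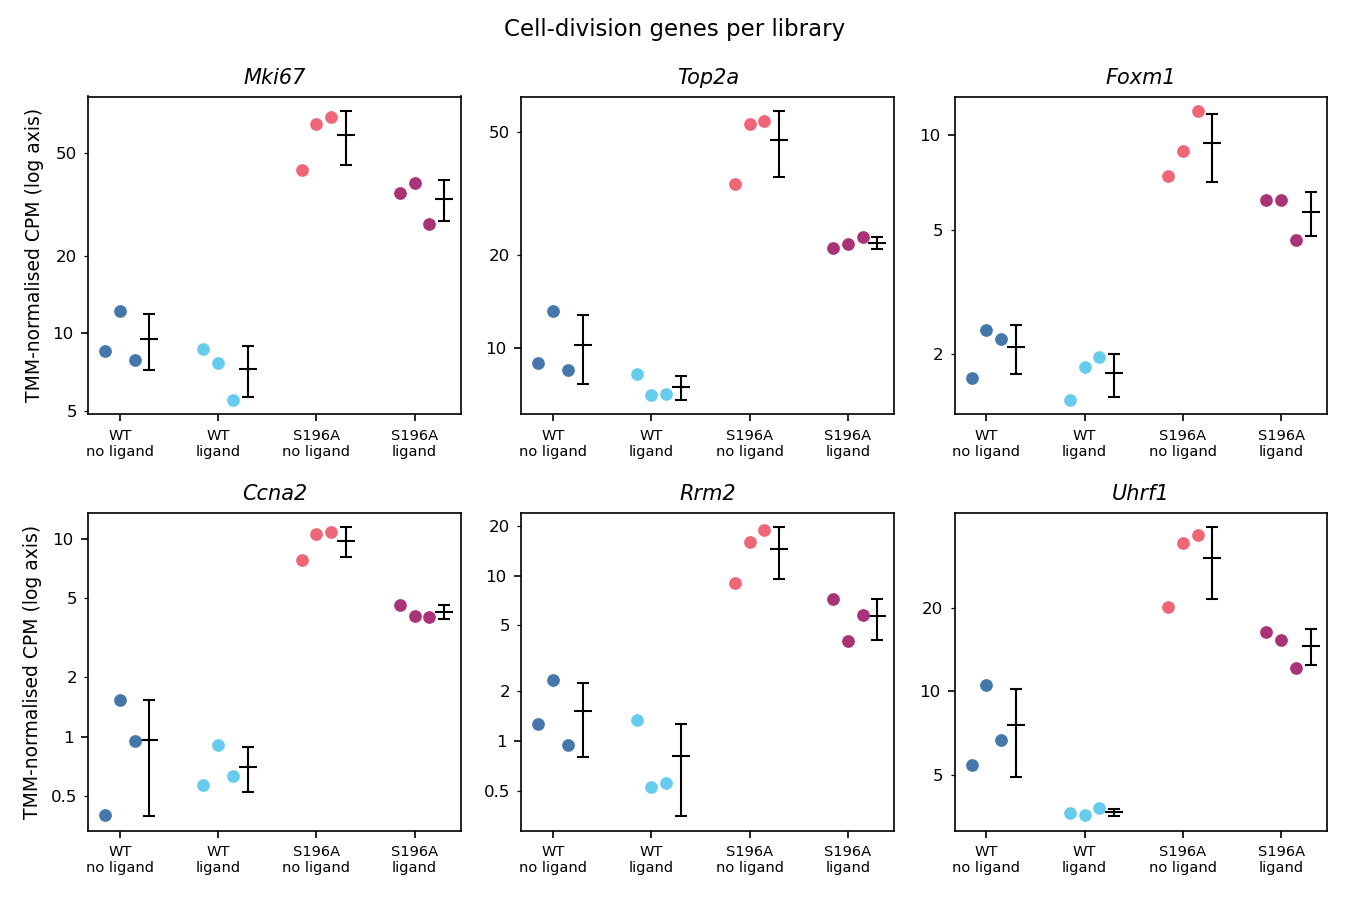
TMM-normalised CPM on log axes of 6 cell-division genes (Mki67, Top2a, Foxm1, Ccna2, Rrm2, Uhrf1) in the 4 groups; points are the 3 libraries of a group, and the dash with bars is the mean ± SD. Mki67 was at 58.8 and 33.2 CPM in S196A basal and S196A ligand against 9.53 and 7.30 in the WT groups, and no S196A library overlapped a WT library in any of the 6 panels.

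Several abundant macrophage transcripts were lower in S196A without ligand. Lyz2 (chromosome 10, 117277331 to 117282321), the macrophage lysozyme gene, was at 5382 ± 210 CPM against 10210 ± 441 in WT (1.90-fold lower, log2 −0.92, SE 0.0586, adjusted p = 1.61e-06). Its near-identical copy Lyz1 rose from 9.73 to 21.8 CPM (adjusted p = 4.49e-05), and reads that fit both copies make these 2 values uncertain. Apoe (chromosome 7, 19696109 to 19699188), which encodes a lipid carrier, was at 6847 ± 1050 CPM against 11440 ± 653 (log2 −0.74, SE 0.0971, adjusted p = 0.000301). C1qa, a complement gene, was at 547 against 1263 CPM (log2 −1.21, SE 0.0850, adjusted p = 4.6e-06). Mertk, which encodes a receptor for dying cells, was at 105 against 177 CPM (log2 −0.75, adjusted p = 5.96e-05). The phagocytosis and efferocytosis list had 5 genes higher, 10 lower and 8 not passed of 23, with 7 higher and 11 lower adjusted over the list alone. Its median was −0.17 (camera adjusted p = 0.0381; adjusted p = 0.316 with an estimated correlation), and the camera call was lost without WT basal 2 (0.0655), WT ligand 3 (0.0602) or S196A basal 2 (0.0793). Macrophage markers had 1 higher, 6 lower and 9 not passed of 16 (2 and 6 adjusted over the list alone), with Mafb at −0.54 and Adgre1 at −0.53. That list's median was −0.12 (camera adjusted p = 0.00358; adjusted p = 0.316 with an estimated correlation). Of 14 alternative activation genes, Klf4 was higher at 0.97 and Il10 (−1.06) and Mrc1 (−0.50) were lower, with the same 1 and 2 adjusted over the list alone. Its median (−0.03) and camera test (Down, adjusted p = 0.698) pointed down while its mean (0.01) did not. Of 7 MHC class II genes 0 passed by edgeR, 0 adjusted over the list alone, 0 by DESeq2 and 0 by limma voom, and 1 had an unadjusted p under 0.05.

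The 10 largest falls under the naming rule were those of the chemokine genes Ccl8, Ccl12 and Ccl7, the acute-phase gene Saa3, the complement genes C4b and Cfb, and Slfn4, Slfn1, Fam71a and Fpr1. The call of Ccl12 (adjusted p = 0.014) was lost in 4 leave-outs, at up to 0.0704 without WT basal 3. Ccl8 (chromosome 11, 82115185 to 82116799) fell 10.7-fold from 18.5 to 1.74 CPM (log2 −3.42, SE 0.377, adjusted p = 8.12e-05). Saa3, an acute-phase gene, fell from 90.7 to 12.7 CPM (log2 −2.84, SE 0.276, adjusted p = 3.89e-05), and Ccl5 fell from 335 to 82.6 CPM (log2 −2.02, SE 0.402, adjusted p = 0.00503). The complement genes C4b and Cfb fell by 2.60 and 2.34 on the log2 scale. The inflammatory list had 0 higher, 8 lower and 10 not passed of 18 (10 lower adjusted over the list alone), with a median of −0.70. Its camera adjusted p was 0.000788, and the adjusted p = 0.371 with an estimated correlation. The 8 fell to 4 without WT basal 1, 2 without WT basal 3, 5 without S196A basal 2 and 3 without S196A basal 3. Interferon-stimulated genes had 1 of 26 members above 0, but Mx1 and Mx2 were the 2 that passed over all genes, against 16 lower adjusted over the list alone. Their median was −0.60 (camera adjusted p = 8.87e-06; adjusted p = 0.492 with an estimated correlation). Mx1 went from 377 to 160 CPM (log2 −1.23, adjusted p = 0.0247). Without WT basal 2, S196A ligand 3 or WT ligand 3 the number called lower became 18, 14 and 8, it was 1 without WT ligand 2, and it was 0 without WT basal 1, WT basal 3, S196A basal 1 or S196A basal 2.

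Some genes that make lipids stood higher in S196A without ligand, while the LXR target list as a group did not pass. Sterol synthesis had 12 higher, 0 lower and 11 not passed of 23 (18 higher adjusted over the list alone), with Mvd at 1.03 and a median of 0.57. Its camera adjusted p was 4.59e-07, and the adjusted p = 0.371 with an estimated correlation. Fatty acid synthesis had 7 higher, 0 lower and 10 not passed of 17 (10 adjusted over the list alone), with a median of 0.35. Its camera adjusted p was 6.36e-05, and the adjusted p = 0.316 with an estimated correlation. Fads2, a desaturase gene, was higher by 1.69 (adjusted p = 0.000869), and Scd1, another desaturase gene, rose from 3.11 to 9.95 CPM (log2 1.67, adjusted p = 0.00336). LXR targets had 5 higher, 3 lower and 16 not passed of 24 (5 and 5 adjusted over the list alone). Their median (−0.01) and camera test (Down, adjusted p = 0.799) were negative and their mean, 0.00 after rounding, was positive, and the 3 lower genes were Apoe, Mertk and Abca1. The LXR and fatty acid lists share Scd1, Scd2, Fasn, Srebf1, Elovl5, Fads1 and Acsl3. Abca1 (chromosome 4, 53030787 to 53159895), which encodes a cholesterol exporter, was at 661 ± 52.7 CPM against 907 ± 6.63 (log2 −0.46, adjusted p = 0.014). That call was lost without WT basal 1 (0.0512), S196A basal 2 (0.0515) or S196A basal 3 (0.0602). Without WT basal 1, WT basal 3, S196A basal 2 or S196A basal 3, the sterol genes called higher numbered 2, 3, 3 and 4, and the LXR targets called higher 1, 2, 2 and 1. LXR targets called lower numbered 5 without WT basal 2. The fatty acid genes called higher numbered 4 without WT basal 1 and 4 without S196A basal 3.

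Genes of energy metabolism and growth control were compared in the same way. Glycolysis and hypoxia had 10 higher, 3 lower and 13 not passed of 26 (17 and 3 adjusted over the list alone), with the oxygen sensor gene Egln3 at 2.24 and the lactate exporter gene Slc16a3 at 0.70. The median was 0.27, the camera adjusted p was 7.6e-05, and the adjusted p = 0.316 with an estimated correlation. The 10 fell to 2 without WT basal 1, 4 without WT basal 3 and 4 without S196A basal 3. Targets of p53 had 1 higher, 6 lower and 9 not passed of 16 (1 and 9 adjusted over the list alone), among them Phlda3 (−1.03) and Plk2 (−0.73). Their median was −0.24 (camera adjusted p = 0.000807; adjusted p = 0.371 with an estimated correlation), and 3 were lower without WT basal 1. Anti-apoptotic genes had 0 higher, 3 lower and 8 not passed of 11 (6 lower adjusted over the list alone), with Bcl2l1 at −0.53. Their median was −0.24 (camera adjusted p = 0.0107; adjusted p = 0.316 with an estimated correlation), and 5 were lower without WT basal 2 or WT ligand 3. Of 16 pro-apoptotic genes 1 was higher (Fas, 0.85; also 1 adjusted over the list alone) and the list did not pass (camera adjusted p = 0.551).

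Over all genes, 1596 passed between the genotypes without ligand, 896 higher and 700 lower, of which 270 and 88 differed more than 2-fold. The 3 libraries of each genotype did not overlap in 1571 of the 1596, and in 33.5% of all tested genes against 10% by chance. Scaled to library totals with no composition factor, 1869 passed and 76.1% of them were higher, against 56.1% with TMM, and the median gene shifted by 0.0771. With the level of interferon-stimulated genes as a covariate 1042 passed. The count was 758 without WT basal 1, 779 without WT basal 3 and 1048 without S196A basal 2. No camera call in either genotype comparison held with an estimated correlation. By fry, which tests whether a list's genes on balance move one way and does not compare them with other genes, 12 lists passed without ligand. Upward these were mitosis (adjusted p = 3.48e-05), DNA replication (0.00367), fatty acid synthesis (0.0107), glycolysis and hypoxia (0.0107), monocyte markers (0.0152), sterol synthesis (0.0354) and heat shock genes (0.043). Downward they were macrophage markers (0.000172), phagocytosis (0.00289), anti-apoptotic genes (0.0107), inflammatory genes (0.0354) and p53 targets (0.0418).

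**Figure D2:**
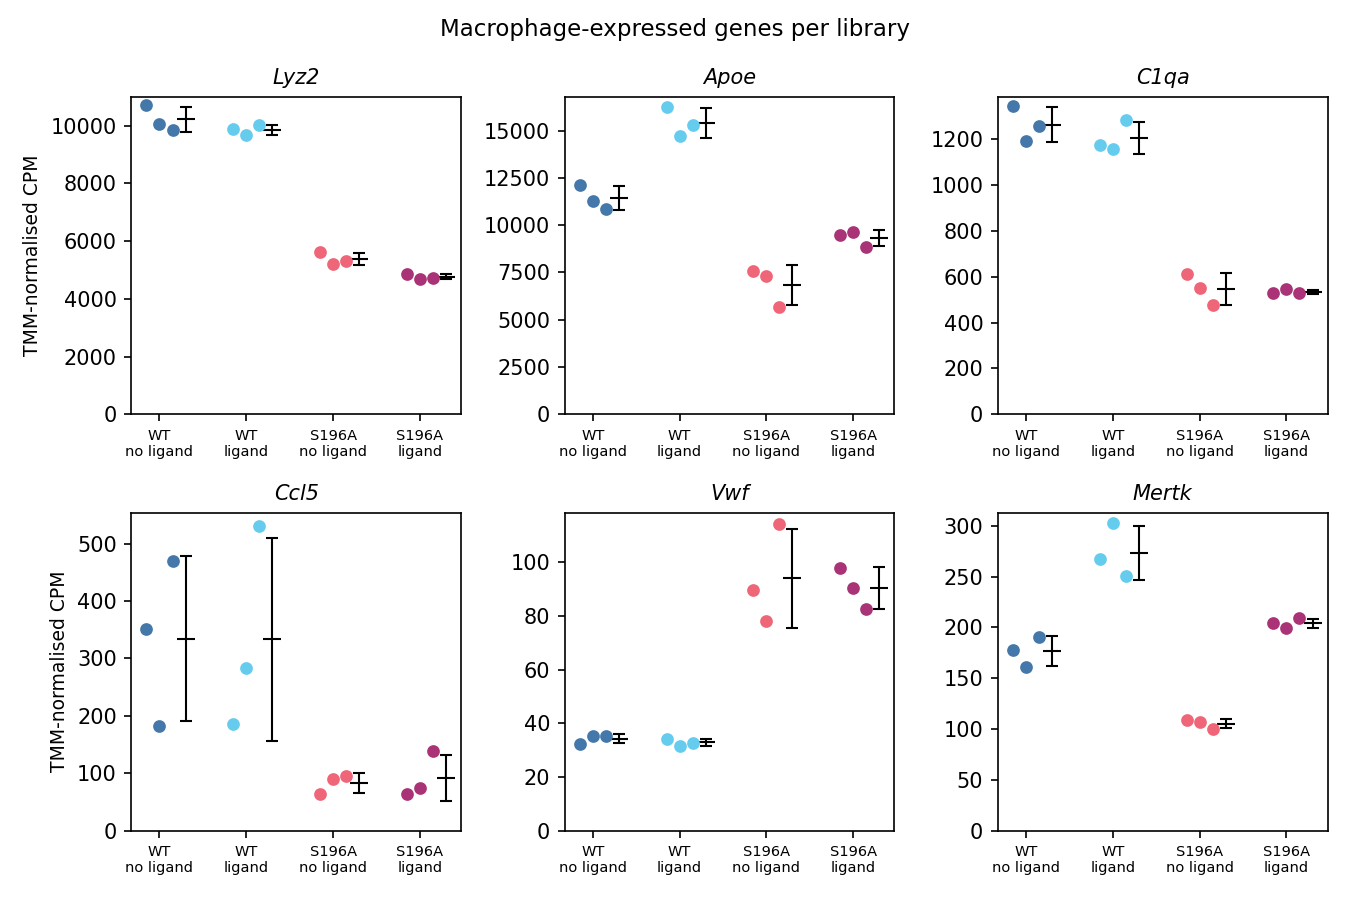
TMM-normalised CPM of Lyz2, Apoe, C1qa, Ccl5, Vwf and Mertk in the 4 groups, on axes that start at 0; points are the 3 libraries of a group, and the dash with bars is the mean ± SD. Lyz2 lay at 5382 and 4765 CPM in the S196A groups against 10210 and 9859 in the WT groups, and Vwf lay at 94.1 and 90.3 against 34.2 and 32.9.

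The same genotype question was asked in cells that had received the ligand, with 6 other libraries. Cell-division genes again stood higher in S196A. Mki67 was at 33.2 ± 6.04 CPM against 7.30 ± 1.61 (4.60-fold, log2 2.20, SE 0.230, adjusted p = 0.00015). Cenpf was 9.94-fold higher (SE 0.371, adjusted p = 0.000215), Foxm1 was higher by 1.69 (adjusted p = 0.000879), and Aspm, Casc5, Ube2c, Bub1 and Rrm2 rose by 2.87 to 3.21 on the log2 scale. The mitosis list had 23 higher, 0 lower and 6 not passed (26 higher and 1 lower adjusted over the list alone) with a median of 1.69. Its camera adjusted p was 2.07e-21, and the adjusted p = 0.191 with an estimated correlation. DNA replication had 15 higher, 0 lower and 18 not passed (17 adjusted over the list alone) with a median of 0.39 (camera adjusted p = 1.88e-07; adjusted p = 0.71 with an estimated correlation). The 15 became 5, 4, 2 and 5 without WT ligand 2, WT ligand 3, S196A ligand 1 and S196A ligand 2, and mitosis genes called higher ranged from 18 to 24 with 1 library left out.

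Several macrophage transcripts were also lower in S196A with ligand, while the inflammatory list did not pass. Lyz2 was at 4765 ± 89.8 CPM against 9859 ± 170 (2.07-fold lower, log2 −1.05, SE 0.0588, adjusted p = 9.71e-07), and its copy Lyz1 was higher by 1.15 (adjusted p = 0.00015). Apoe was at 9339 ± 417 against 15420 ± 795 CPM (log2 −0.72, adjusted p = 7e-04), and C1qa was at 534 against 1205 CPM (log2 −1.18). Ccl8 (−2.75, adjusted p = 0.000485) and Saa3 (−2.54, adjusted p = 0.000169) were lower, and so was the formyl peptide receptor gene Fpr1 (−2.13). Macrophage markers had 1 higher, 6 lower and 9 not passed (2 and 6 adjusted over the list alone), a median of −0.15 and a camera adjusted p of 0.00954 (adjusted p = 0.456 with an estimated correlation). Phagocytosis and efferocytosis had 4 higher, 8 lower and 11 not passed (6 and 8 adjusted over the list alone). Its median was 0.00, but its mean (−0.03) and camera test (Down, adjusted p = 0.367) were negative, and 5 genes were lower without S196A ligand 1 or 2. Interferon-stimulated genes had 0 higher, 11 lower and 15 not passed (22 lower adjusted over the list alone), with Mx1 at −1.25 and Ifit3 at −1.03. Their median was −0.73 (camera adjusted p = 2e-08; adjusted p = 0.71 with an estimated correlation). The 11 moved with many single libraries, to 0 without WT ligand 3, S196A ligand 1 or S196A ligand 2, to 3, 4, 4 and 4 without WT basal 1, WT ligand 2, S196A basal 1 and S196A basal 2, to 7 without S196A basal 3, to 19 without WT ligand 1, to 21 without WT basal 2, and to 23 without S196A ligand 3. The calls of Mx1 and Ifit3 were both lost without WT ligand 3 (0.113 and 0.147), S196A ligand 1 (0.109 and 0.129) or S196A ligand 2 (0.12 and 0.141). Inflammatory genes had 0 higher and 2 lower of 18 (1 and 4 adjusted over the list alone; camera adjusted p = 0.108). The 2 became 4 without WT basal 2 or WT ligand 1 and 5 without S196A ligand 3. It became 1 without WT basal 1 or any 1 of the S196A basal libraries, and 0 without WT ligand 3, S196A ligand 1 or S196A ligand 2.

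Lipid and metabolic lists were compared between the genotypes in the presence of ligand as well. Sterol synthesis had 3 higher and 0 lower of 23 (5 adjusted over the list alone), a median of 0.28 and a camera adjusted p of 0.00818 (adjusted p = 0.742 with an estimated correlation). That call was lost without WT ligand 3 (0.0804). Fatty acid synthesis had 2 higher and 0 lower of 17 (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0506). LXR targets had 3 higher, 4 lower and 17 not passed (4 and 7 adjusted over the list alone), with Tgm2 at 0.38, Mertk at −0.42 and a camera adjusted p of 0.426. Abca1 was at 2862 ± 61.8 CPM in S196A and 2841 ± 546 in WT. Glycolysis and hypoxia had 7 higher, 3 lower and 16 not passed (15 and 3 adjusted over the list alone), a median of 0.25 and a camera adjusted p of 0.00237 (adjusted p = 0.71 with an estimated correlation). These small counts followed single libraries: without S196A ligand 2, for example, 0 sterol genes, 0 LXR targets and 2 glycolysis genes were called higher, and without S196A ligand 3 these numbered 5, 3 and 13. Of 16 p53 targets 2 were lower (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0506). Their lower count ran from 0, without WT ligand 3, to 3 with 1 library left out. By camera, p53 targets and fatty acid synthesis each passed in 5 leave-outs and anti-apoptotic genes in 3. Anti-apoptotic genes had 2 lower of 11 (5 adjusted over the list alone; camera adjusted p = 0.0506) and lysosome genes 1 higher of 26 (1 adjusted over the list alone; camera adjusted p = 0.774). Of 16 pro-apoptotic genes 0 passed by edgeR, 0 adjusted over the list alone, 0 by DESeq2 and 0 by limma voom, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.667).

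With ligand, 1590 genes passed between the genotypes, 847 higher and 743 lower. Groups did not overlap in 32.2% of tested genes against 10% by chance. Of the genes that passed without ligand, 541 of 896 were also called higher and 401 of 700 also lower, against 65.8 and 45.1 for independent lists, and 2 genes passed in opposite directions. The sign was the same for 880 of the 896 and 671 of the 700. No library entered both comparisons, but both came from 1 fit, and the libraries of a genotype may share mice. The 2 comparisons may therefore not be independent. Library totals alone gave 1939 calls, 76.3% of them higher against 53.3% with TMM. By fry 6 lists passed with ligand: mitosis (adjusted p = 0.000248), DNA replication (0.0423) and glycolysis and hypoxia (0.0423) upward, and macrophage markers (0.000372), phagocytosis (0.0423) and anti-apoptotic genes (0.0497) downward. A fit of only these 2 groups gave 913 calls, and a fit with the level of interferon-stimulated genes as a covariate 455. The number of genes that passed fell to 631 without WT ligand 3, 574 without S196A ligand 1 and 509 without S196A ligand 2.

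**Figure D3:**
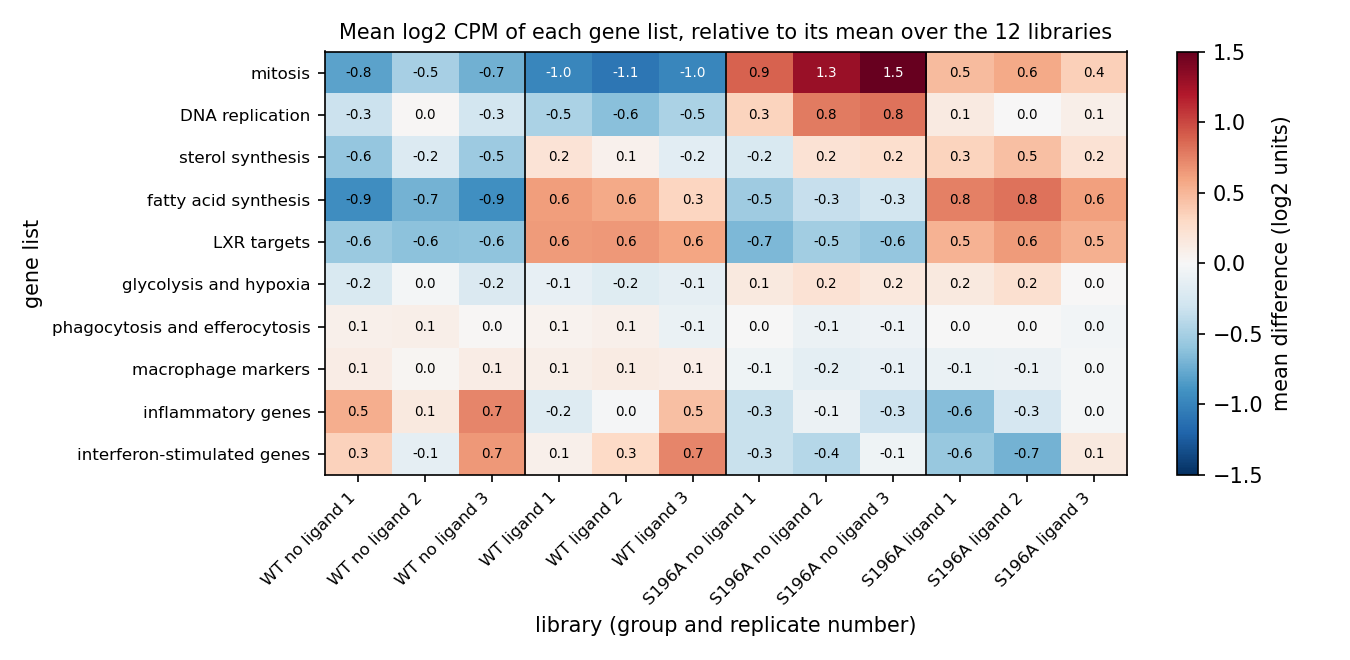
Mean log2 CPM of 10 gene lists (lines) in the 12 libraries (columns), each relative to the list's mean over all libraries; red is higher and blue lower, and the number is the difference in log2 units. Mitosis genes lay above their mean in all 6 S196A libraries (by 0.36 or more) and below it in all 6 WT libraries, and the LXR target list split by ligand instead.

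The ligand comparison in WT asked which genes a ligand of LXR changed. The 10 largest rises under the naming rule were those of Scd1, Scd2, Apoc1, Fasn, Srebf1, AI427809, Fads2, Abca1, Atg9b and Abcg1, of which AI427809 was not called without WT basal 1 (0.0621). Scd1 (chromosome 19, 44394455 to 44407879), a desaturase gene, rose 40.5-fold from 3.11 to 127 CPM (log2 5.34, SE 0.265, adjusted p = 4.04e-08). Scd2 rose 22.5-fold from 41.9 to 941 CPM (SE 0.198, adjusted p = 1.88e-08). Srebf1 (chromosome 11, 60199089 to 60222581), which drives fatty acid genes, rose 5.46-fold from 87.8 to 480 CPM (SE 0.0979, adjusted p = 1.13e-08). Abca1 rose 3.13-fold from 907 ± 6.63 to 2841 ± 546 CPM (SE 0.112, adjusted p = 1.15e-06), and Abcg1 (chromosome 17, 31057675 to 31117988), another cholesterol exporter gene, rose by 1.52 (SE 0.0973, adjusted p = 6.52e-07). Mylip, which marks the low-density lipoprotein receptor for breakdown, rose by 1.48 and Mertk by 0.63. Among 24 LXR targets 17 rose, 1 fell and 6 did not pass (19 and 2 adjusted over the list alone), and Tgm2 was the 1 that fell (−0.59, adjusted p = 0.00105). The list's median was 0.70 (camera adjusted p = 1.82e-33), and the call held at an adjusted p = 1.86e-05 with an estimated correlation. Fatty acid synthesis had 10 higher, 0 lower and 7 not passed of 17 (12 adjusted over the list alone), a median of 0.65, and a camera adjusted p of 4.59e-28 that held at an adjusted p = 0.0138 with an estimated correlation. Sterol synthesis had 6 higher, 0 lower and 17 not passed of 23 (13 adjusted over the list alone), with Insig1 at 1.09 and Pmvk at 0.94. Its median was 0.44 (camera adjusted p = 4e-13; adjusted p = 0.34 with an estimated correlation), and 2, 3, 2 and 3 sterol genes were higher without WT basal 1, WT basal 3, WT ligand 1 and WT ligand 2. Ldlr rose by 0.37 (SE 0.0787, adjusted p = 0.026), a call lost without any 1 of the 6 WT libraries (0.0521 to 0.106). Apoe rose by 0.43 (adjusted p = 0.037), a call lost in 8 of the 12 leave-outs, at up to 0.161 without WT ligand 1.

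Fewer transcripts fell with ligand in WT, among them chemokine and early response genes. Cxcl2, a neutrophil chemokine gene, fell from 36.9 to 8.24 CPM (log2 −2.15, adjusted p = 0.00174), Dusp1, a phosphatase gene of the early response, from 366 to 140 CPM (log2 −1.38, adjusted p = 0.00136), and the chemokine receptor gene Cx3cr1 from 14.5 to 3.73 CPM (SE 0.359, adjusted p = 0.00906). Fam71a (chromosome 1, 191162584 to 191164817) fell from 4.38 to 0.741 CPM (log2 −2.55, adjusted p = 0.000404). Inflammatory genes had 0 higher, 2 lower and 16 not passed of 18 (2 adjusted over the list alone), a median of −0.21 and a camera adjusted p of 0.000305 (adjusted p = 0.429 with an estimated correlation). Only 1 was lower without WT basal 1, WT basal 3, WT ligand 1 or WT ligand 2. Immediate early genes had 0 higher, 2 lower and 11 not passed of 13 (9 adjusted over the list alone), a median of −0.34 and a camera adjusted p of 2.5e-05 (adjusted p = 0.429 with an estimated correlation). Mitosis had 0 higher, 1 lower and 28 not passed (1 adjusted over the list alone), with Kif23 at −0.65, a median of −0.43 and a camera adjusted p of 1.01e-05 (adjusted p = 0.429 with an estimated correlation). DNA replication had 0 of 33 passed by edgeR (0 adjusted over the list alone, 10 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma voom), a median of −0.30 and a camera adjusted p of 6.21e-07 (adjusted p = 0.429 with an estimated correlation), and 1 gene was lower without S196A basal 1. Over all genes 209 passed, 123 higher and 86 lower, against 1366 at an unadjusted p under 0.05. Groups did not overlap in 16.3% of tested genes against 10% by chance. The count fell to 103 without WT basal 1 and 108 without WT ligand 1, and it was 124 in a fit of only the WT groups and 530 with the interferon covariate.

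**Figure D4:**
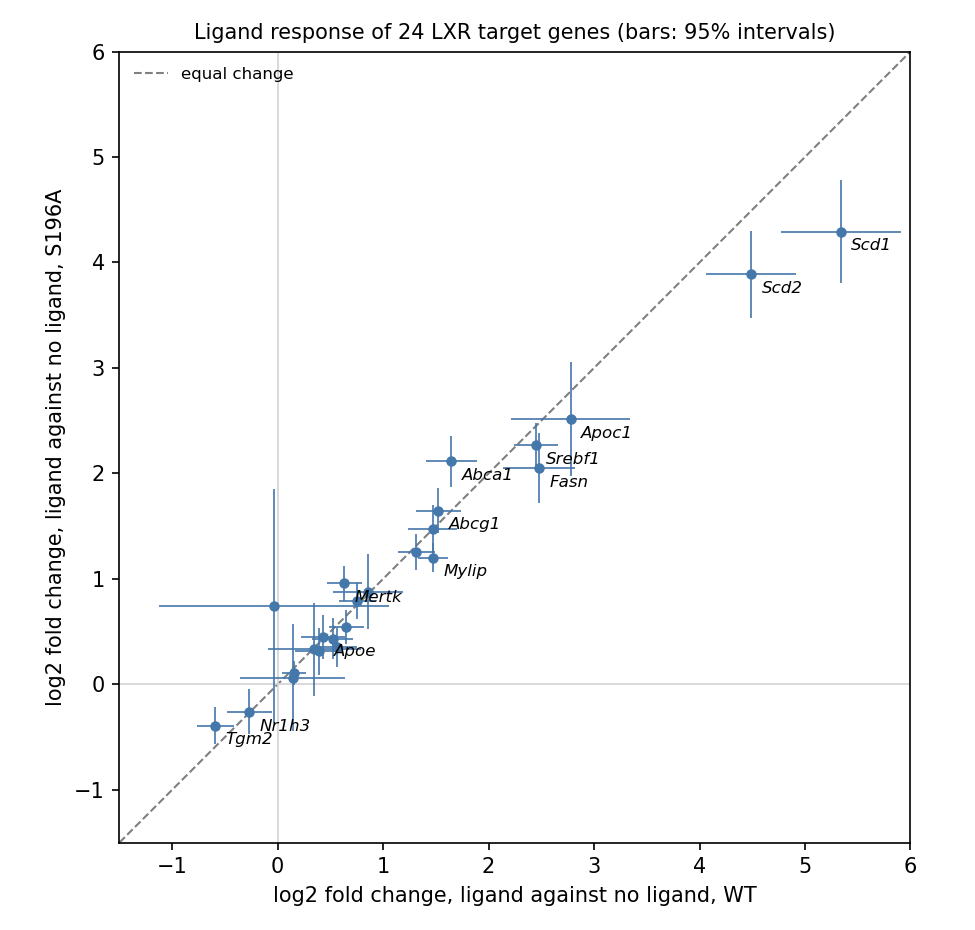
Log2 fold change with ligand of 24 LXR target genes in WT (horizontal axis) and S196A (vertical axis), each point a gene with 95% intervals, and the dashed line marking equal change. Scd1 lay at 5.34 and 4.29, below the line, and Abca1 at 1.65 and 2.11, above it.

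The same ligand question in S196A gave a similar set of rising genes. Scd1 rose 19.6-fold from 9.95 to 195 CPM (log2 4.29, SE 0.227, adjusted p = 1.37e-07), Scd2 14.8-fold from 69.3 to 1025 CPM (adjusted p = 8.59e-08) and Srebf1 4.82-fold from 99.6 to 480 CPM (adjusted p = 2.74e-08). Abca1 rose 4.33-fold from 661 ± 52.7 to 2862 ± 61.8 CPM (SE 0.113, adjusted p = 1.37e-07), Abcg1 3.13-fold (adjusted p = 3.34e-07) and Mertk by 0.96 (adjusted p = 7.31e-06). Apoe rose by 0.45 (SE 0.0968, adjusted p = 0.032), a call lost without S196A basal 2 or 3 or any S196A ligand library (0.052 to 0.136). LXR targets had 16 higher, 1 lower and 7 not passed (18 and 2 adjusted over the list alone), a median of 0.84 and a camera adjusted p of 1.5e-34, which held at an adjusted p = 1.65e-05 with an estimated correlation. Tgm2 was the 1 lower (−0.39, adjusted p = 0.0245), and the number lower was 0 without S196A basal 2 or 3 or any S196A ligand library. Fatty acid synthesis had 8 higher, 0 lower and 9 not passed (10 adjusted over the list alone), a median of 0.55 and a camera adjusted p of 9.4e-23, which held at an adjusted p = 0.0271 with an estimated correlation. Sterol synthesis had 2 higher, 0 lower and 21 not passed (5 adjusted over the list alone), with Insig1 at 0.84 and a median of 0.30. Its camera adjusted p was 3.56e-06, with an adjusted p = 0.623 with an estimated correlation and 0.0581 by camera without S196A basal 1.

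Among cell-division genes, 9 of 29 mitosis genes and 12 of 33 DNA replication genes fell with ligand in S196A. Mki67 went from 58.8 ± 13.9 to 33.2 ± 6.04 CPM (log2 −0.83, SE 0.188, adjusted p = 0.0428), a call lost in 7 of the 12 leave-outs and at up to 0.213 without S196A basal 2. Top2a, a gene of chromosome untangling, fell from 46.9 to 21.9 CPM (log2 −1.10, SE 0.166, adjusted p = 0.0032), and Kif23 fell from 48.2 to 32.4 CPM (log2 −0.57, adjusted p = 0.00353). Mitosis genes had 0 higher, 9 lower and 20 not passed (28 lower adjusted over the list alone), with 0 of 29 positive and a median of −0.78. Their camera adjusted p was 9.4e-23, and the adjusted p = 0.0572 with an estimated correlation. The 9 became 17 without S196A basal 1, 2 without S196A basal 2, 3 without S196A basal 3, 4 without S196A ligand 1, 4 without S196A ligand 2 and 3 without S196A ligand 3. DNA replication genes had 0 higher, 12 lower and 21 not passed (25 lower adjusted over the list alone), with Mcm7 at −0.75 and Fen1 at −0.55. Their median was −0.52 (camera adjusted p = 3.99e-19; adjusted p = 0.105 with an estimated correlation). The 12 became 7 without WT basal 1, 1 without S196A basal 2, 0 without S196A basal 3, 1 without S196A ligand 1, 0 without S196A ligand 2 and 5 without S196A ligand 3. The calls of Mcm7 and Fen1 were both lost without S196A basal 3 (0.0523 and 0.0769). Monocyte markers moved in the same direction, with 0 higher, 1 lower and 7 not passed of 8 (3 lower adjusted over the list alone), a camera adjusted p of 0.0296 (adjusted p = 0.105 with an estimated correlation) and a fry adjusted p of 0.0316. That camera call was lost without S196A basal 1, S196A basal 2 or S196A ligand 1, at up to 0.199 without the last. Vcan was the 1 lower, from 37.0 to 17.3 CPM (log2 −1.10, adjusted p = 0.0126), and was not called without S196A basal 2 (0.0711), S196A basal 3 (0.0504) or S196A ligand 1. The number lower was 2 without WT ligand 2 or S196A basal 1. Cx3cr1 fell from 46.2 to 9.80 CPM (log2 −2.24, adjusted p = 0.000614). Over all genes 192 passed, 100 higher and 92 lower, against 1380 at an unadjusted p under 0.05, and 69 and 22 of them had also passed in WT against 1.07 and 0.686 for independent lists. No gene passed in opposite directions under ligand, and groups did not overlap in 18.2% of tested genes against 10% by chance. With the interferon covariate 576 passed. The count fell to 92 without S196A basal 2, 107 without S196A basal 3, 81 without S196A ligand 1, 95 without S196A ligand 2 and 114 without S196A ligand 3.

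The last comparison asked whether the ligand response itself differed between the genotypes. Fam71a passed, with 4.38 CPM in WT basal, 0.741 in WT ligand, 0.683 in S196A basal and 1.84 in S196A ligand (log2 difference 3.94, SE 0.461, adjusted p = 0.0092). The long non-coding RNA gene F630028O10Rik (chromosome X, 96239926 to 96243642), a transcript that also carries the name of a microRNA, was the other (log2 difference −1.14, SE 0.149, adjusted p = 0.0169). It was at 29.7 ± 3.72 CPM in WT basal, 57.4 ± 1.28 in WT ligand, 37.1 ± 1.65 in S196A basal and 32.5 ± 4.88 in S196A ligand, and it was chosen after its values were seen. These were the 2 of 11535 genes that passed, against 475 at an unadjusted p under 0.05, 3 by DESeq2 and 2 by limma voom. The count was 0 without WT ligand 2 or WT ligand 3 and 1 without WT ligand 1 or without any 1 of the S196A basal libraries, and Fam71a reached 0.0637 without WT ligand 2. Of 24 LXR targets 0 passed by edgeR over all genes, adjusted over the list alone, by DESeq2 or by limma voom, and 5 had an unadjusted p under 0.05, with Scd1 at −1.05, Abca1 at 0.47, Mertk at 0.33 and a list median of −0.05 (camera adjusted p = 0.427). Mitosis genes had a median of −0.45, and 0 passed by the same 4 counts against 4 at an unadjusted p under 0.05 (camera adjusted p = 1.75e-07; adjusted p = 0.674 with an estimated correlation). The falls of cell-division genes in S196A alone are therefore not shown to differ from those in WT gene by gene. Cxcl2 was the inflammatory gene that passed adjusted over the list alone (log2 difference 1.85), and its adjusted p over all genes was 0.722.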

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

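The tests of a single library and of the interferon state for cell-division genes, and the tests of Lyz2 and of the interferon-stimulated genes, were chosen only after the results were seen.

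Mitosis genes stood higher in S196A in both ligand states, with medians of 2.15 and 1.69 on the log2 scale, and Mki67 was higher in 6 of 6 S196A libraries. Dividing granulocyte precursors, red cell precursors, B cells or mast cells would bring their abundant transcripts, but the summed level of 15 of these went from 2.00 to 1.60 CPM, a change of −0.392, while Mki67 alone gained 49.3 CPM. No single library carried the difference, since at least 18 mitosis genes were higher whichever library was left out, nor did a shared interferon state, since the smaller median was still 1.62 with that state as a covariate. That sum left out monocytes and megakaryocytes, whose markers moved unevenly: without ligand Vcan (37.0 against 9.25 CPM), Ccr2 (218 against 122) and Vwf (94.1 against 34.2) were higher while Ly6c2 (3.00 against 4.86), Pf4 (37.3 against 32.5) and Ppbp (0.733 against 0.739) did not pass, and with ligand the monocyte median was −0.11 while 4 of 4 megakaryocyte markers were higher (2 without WT ligand 2, 1 without WT ligand 3 or S196A ligand 2), among them Pf4 (adjusted p = 0.0133) and Ppbp (0.0194), so a part from these lineages was not settled. More dividing macrophages through the S196A change, and a difference in culture time or cell density between the genotypes, may each give this pattern and stay open and untested.

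Lyz2 was 1.90-fold lower in S196A without ligand and 2.07-fold lower with ligand, lower in 6 of 6 S196A libraries. A lower share of macrophages would lower all their markers alike. The median of 14 other macrophage markers was −0.12 without ligand (SD 0.342) and −0.15 with ligand (SD 0.327), against −0.92 and −1.05 for Lyz2. Of all 16 markers tested, 6 were called lower in each state, Lyz2 included, and the 1 called higher was Lyz1. A lower share may therefore add to the fall of Lyz2, but the median marker fell by much less. Reads counted under the copy Lyz1 instead are too few, since Lyz1 gained 12.1 CPM, 0.251% of the 4832 CPM that Lyz2 lost. Any reads left out of the counts because they fit both copies would not show in this test. Loss of 1 of 2 expressed copies predicts a ratio near 0.5, and the ratio was 0.527 (95% interval 0.483 to 0.575) without ligand and 0.483 (0.443 to 0.528) with ligand. The intervals included 0.5 in both states for 76 of the 401 genes called lower in both, Cd4 among them. Of these 76, 3 genes, Lyz2 included, had intervals up to 2 times as wide as those of Lyz2. A disrupted Lyz2 allele in the S196A mice is therefore a candidate explanation and no more than that, since the labels state no change at Lyz2. Lower expression of both copies through the S196A change stays open and untested.

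Of 26 interferon-stimulated genes 2 passed as lower in S196A without ligand and 11 with ligand (medians −0.60 and −0.73), and the list did not pass with an estimated correlation (adjusted p = 0.492 and 0.71) or by fry (0.148 and 0.11). No single library carried the direction, since the highest median was −0.43 whichever library was left out. The mean level was lower in S196A in 6 of 6 same-number comparisons, with a mean difference of −0.66, and an exact two-sided permutation of the genotype within each ligand state gave p = 0.02 over 400 permutations, whose smallest possible p is 0.005. That permutation takes the libraries as independent, and if both libraries of a genotype and number came from 1 mouse, only 20 permutations are left, with p = 0.1 and a smallest possible p of 0.1, so chance between animals stays open. The difference may be one of culture rather than of genotype, these cannot be told apart here, and an effect of the S196A change stays open and untested.

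The ligand response of Fam71a differed between the genotypes by a test of the difference itself (log2 3.94, SE 0.461, adjusted p = 0.0092): Fam71a fell in WT and stood at 0.683 CPM without and 1.84 CPM with ligand in S196A, and all 3 WT ligand libraries lay below all 3 WT basal libraries. F630028O10Rik differed the other way (log2 −1.14, SE 0.149, adjusted p = 0.0169), rising 1.93-fold with ligand in WT (adjusted p = 0.000172) and not passing in S196A (log2 −0.19, adjusted p = 0.549). The call of Fam71a was lost without WT ligand 2 (adjusted p = 0.0637) or WT ligand 3 (0.0585). That of F630028O10Rik was lost without any 1 of the 3 WT ligand or 3 S196A basal libraries. By camera, the ligand response also differed for mitosis (adjusted p = 1.75e-07, median −0.45), DNA replication (adjusted p = 9.49e-05, median −0.18), fatty acid synthesis (adjusted p = 0.00137, median −0.11), sterol synthesis (adjusted p = 0.00193, median −0.25) and immediate early genes (adjusted p = 0.000796, median 0.16, 13 of 13 positive). None of these 5 held with an estimated correlation (adjusted p = 0.674 for each) or by fry (adjusted p = 0.822 for each). By camera the sterol synthesis call was lost in 5 of the 12 leave-outs: without WT basal 1 (0.0723), WT ligand 1 (0.0989), S196A basal 2 (0.0687), S196A basal 3 (0.14) or S196A ligand 3 (0.0794). The fatty acid synthesis call was lost without WT ligand 2 (0.0529) or S196A ligand 3 (0.0583), and that of immediate early genes without S196A ligand 3 (0.0666). Xist, a transcript of female cells that lay below the expression filter, had 75 reads in S196A basal 1 and 1 to 6 reads in the other 11 libraries. The Y-linked Ddx3y was at 74.8 CPM in that library and at 65.5 to 82.1 CPM in the others, and the source of the Xist reads was not tested.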

How the results depend on the processing

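Fits with 2 libraries left out together (WT basal 2 and S196A ligand 3, which lay closest to the other genotype on the first principal component) and with the level of interferon-stimulated genes as a covariate were chosen after seeing the data. With 1 library left out, the calls ranged from 758 to 2052 between the genotypes without ligand, from 509 to 1951 with ligand, from 103 to 229 for ligand in WT, from 81 to 247 for ligand in S196A and from 0 to 2 for the difference. DESeq2 gave 1659, 1657, 299, 288 and 3, and limma voom 1577, 1549, 199, 198 and 2. Fits of only the 2 groups compared gave 913 calls between the genotypes with ligand, 885 of them among the 1590, and 124 for ligand in WT, 118 of them among the 209, with fewer libraries behind the spread. Such fits gave 1752 calls between the genotypes without ligand, against 1596, and 187 for ligand in S196A, against 192. With the interferon covariate the counts were 1042 without ligand and 455 with ligand between the genotypes, 530 for ligand in WT and 576 for ligand in S196A. That level was itself lower in S196A (mean difference −0.66), so the covariate overlaps with the genotype and can take up part of that contrast. The cause of the changed counts was not tested. Under that covariate the MHC class II list without ligand turned from up to down (adjusted p = 0.0107) and Kdr with ligand turned from lower to higher (log2 0.398); the cause was not tested. A replicate block gave 2233, 2364, 310, 367 and 2 calls, and a replicate block within genotype gave 293 for ligand in S196A. The libraries share only a number, and same-number correlations of the deviations from the group means ran from −0.345 to 0.425, not all above 0.1, and not every library correlated best with its own number. Between WT ligand and S196A ligand all 3 were above 0.1 (0.134, 0.137 and 0.362), but number 1 correlated better with another number (0.245). The block moved that comparison from 1590 to 2364 calls. Between WT basal and S196A basal each WT library correlated best with its own number. These values were 0.048, 0.14 and 0.139, against −0.014, 0.006 and −0.047 for the best other number. The block moved that comparison from 1596 to 2233 calls. Whether the numbers pair the libraries is therefore not settled. With both libraries left out together, 28 mitosis genes were higher without ligand and 22 with ligand of 30 tested, and 5 were lower with ligand in S196A, while 21 and 25 of 26 interferon-stimulated genes were lower between the genotypes without and with ligand. Over the planned and added alternatives other than leaving out 1 library, 5972 values of named genes stayed on their side of the threshold. Their direction was compared only where the gene was called in both fits. The call was lost for 129 values and gained for 234, and for lists these were 625, 63 and 31. With 1 library left out these were 6891, 391 and 86 for genes and 1378, 20 and 42 for lists. These totals include values that never passed. Of the named genes that passed, 22 of 85 between the genotypes without ligand and 38 of 78 with ligand lost the call in at least 1 leave-out. So did 16 of 38 for ligand in WT, 23 of 39 for ligand in S196A and 1 of 1 for the difference. Depth set a floor of 0.185 to 0.280 CPM, so genes such as Car2 at 0.202 CPM were read near the limit.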

Other observations

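The tests of the replicate-number state were chosen only after the result was seen.

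Lists of other lineages and states, for which the genotypes were compared in the same way, held a few genes that moved far. Vwf, a gene of vessel wall and platelets, was at 94.1 CPM in S196A basal against 34.2 in WT basal (log2 1.46, SE 0.116, adjusted p = 9.56e-06) and at 90.3 against 32.9 with ligand (adjusted p = 1.97e-05). Of 9 megakaryocyte markers 4 were tested. Of these 1 was higher without ligand (1 adjusted over the list alone) and 4 with ligand (4 adjusted over the list alone). The count with ligand was 2 without WT ligand 2 and 1 without WT ligand 3 or S196A ligand 2. Without WT basal 2 the count without ligand was 2. Vcan, a matrix gene of monocytes, was at 37.0 CPM in S196A basal against 9.25 (adjusted p = 7.03e-05), and the monocyte receptor gene Ccr2 was at 218 against 122 (adjusted p = 0.00112). Monocyte markers had 3 higher, 1 lower and 4 not passed of 8 (3 and 1 adjusted over the list alone; camera adjusted p = 0.232), with 0 lower without S196A basal 2. Dcstamp, a gene of cell fusion in osteoclasts, was at 37.8 CPM in S196A basal against 9.84 (adjusted p = 0.00171), while 1 of 8 osteoclast markers was higher over all genes (3 adjusted over the list alone; camera adjusted p = 0.282; 3 called without WT basal 2 and 2 without WT ligand 3). With ligand in S196A, Acp5 (log2 −0.97, adjusted p = 0.0073) and Ocstamp were the 2 osteoclast markers that fell (4 adjusted over the list alone; camera adjusted p = 0.000488; adjusted p = 0.105 with an estimated correlation). The call of Ocstamp (adjusted p = 0.0479) was lost in 8 of the 12 leave-outs, at up to 0.222 without S196A basal 2. In WT the osteoclast list also moved down with ligand, with 0 of 8 called and a median of −0.40. Its camera adjusted p there was 0.00539 (adjusted p = 0.34 with an estimated correlation). That camera call was lost without WT basal 2 (0.0687) or WT ligand 3 (0.0944).

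Values in this paragraph compare the genotypes without ligand unless stated. Cd4, the 1 T and NK cell marker tested, was at 13.2 CPM in S196A basal against 29.2 (log2 −1.15, adjusted p = 0.00142), lower also adjusted over the list alone. Stromal and fibroblast markers had 0 higher, 2 lower and 8 not passed of 10 (6 lower adjusted over the list alone), with Fbn1 at −1.13, a median of −0.83 and a camera adjusted p of 0.0127 (adjusted p = 0.4 with an estimated correlation). The 2 became 5 without WT ligand 3, 1 without S196A basal 3 and 4 without S196A ligand 1. Immediate early genes had 0 higher, 4 lower and 9 not passed of 13 (5 lower adjusted over the list alone). Dusp1 was at −1.01, and the camera adjusted p was 0.00309 (adjusted p = 0.4 with an estimated correlation). Only 2 were lower without WT basal 1, WT basal 3 or S196A basal 2. With ligand this list had 0 higher and 1 lower, a median of 0.00 and a camera adjusted p of 0.774. The unfolded protein and integrated stress response list had 5 higher, 4 lower and 9 not passed of 18 (7 and 6 adjusted over the list alone; camera adjusted p = 0.799), with Ppp1r15a at −0.52, and the higher count was 0 to 3 whichever of the 6 libraries compared was left out (0 without WT basal 1). The lower count was 2 without WT basal 1, S196A basal 2 or S196A basal 3 and 1 without WT basal 3. With ligand 0 genes of that list were higher and 2 lower (camera adjusted p = 0.76). Of 7 neutrophil and granulocyte precursor markers Mmp8 was higher (0.69) and Csf3r lower (−0.31), also adjusted over the list alone (camera adjusted p = 0.551), with 2 lower without S196A basal 2. Itgax (1.19) was the 1 of 6 dendritic cell markers that was higher (1 adjusted over the list alone; camera adjusted p = 0.799), and its adjusted p was 0.0578 without WT basal 1. Heat shock genes had 2 higher of 8 (2 adjusted over the list alone; camera adjusted p = 0.229), with Bag3 at 0.44, and lysosome genes 2 higher of 26 (1 adjusted over the list alone; camera adjusted p = 0.8), with Tfeb at 0.22. Without WT basal 1 both counts became 1, as did the heat shock count without S196A basal 3. The lysosome count became 0 without WT basal 3, S196A basal 1 or S196A basal 3 and 1 without WT ligand 1, S196A ligand 1 or S196A ligand 2, and 4 lysosome genes were lower without WT basal 2. B cell markers (2 tested), mast cell and basophil markers (2), endothelial markers (3) and the erythroid marker Car2 had 0 called by edgeR, DESeq2 and limma voom without ligand; adjusted over the list alone 1 endothelial marker passed, and 2 endothelial markers had an unadjusted p under 0.05. Without S196A ligand 1, 1 endothelial marker was lower over all genes. Car2 was higher with ligand in S196A, at 1.48 against 0.202 CPM (adjusted p = 0.0118), a call lost without S196A basal 2 (0.0743), S196A ligand 1 (0.0509) or S196A ligand 2. DESeq2 did not call Car2 there, and limma voom did. Of 13 mitochondrially encoded genes 0 are listed in the files.

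Replicate 3 had the highest level of interferon-stimulated genes in all 4 groups, with mean deviations from the group mean of −0.119, −0.245 and 0.365 for numbers 1, 2 and 3. An exact permutation of the numbers within groups gave p = 0.0185 over 216 arrangements, whose smallest possible p is 0.00463. Libraries with the same number may therefore share a state, such as a day of culture. Within numbers, the level was lower in S196A in 6 of 6 pairs, by −1.01 to −0.293 log2 units.

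Genes near an edited locus can differ through linked strain variants. This was tested around Nr1h3, Ldlr and Lyz2, although the labels state no change at Lyz2. Within 10 Mb of these loci, 18 of 222 genes (8.11%) were called in both genotype comparisons, against 893 of 10870 (8.22%) elsewhere (one-sided Fisher's exact p = 0.559). The 3 windows together therefore held no higher share of calls than the rest of the genome. They hold 222 genes, so the test cannot speak for the calls elsewhere. It pooled the loci, and Ldlr was lacking in both genotypes, so a linked segment at 1 locus is not excluded. The counts per locus were 4 of 63 for Nr1h3, 8 of 65 for Lyz2 and 6 of 94 for Ldlr.

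A smaller or larger response of LXR targets to ligand in S196A was tested as the mean difference of the log2 response over the list, which was −0.062. In 100 regroupings of the ligand labels it ran from −1.01 to 0.884 and was as large in 54, but those regroupings mix treated with untreated libraries, so whether the S196A change may alter the size of the response cannot be told from this test.

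For each comparison of 2 groups the 6 libraries were also split in the 10 possible ways. The real split was the 1 that gave as many calls in each, with 1596, 1590, 209 and 192 against a highest other count of 0, and 10 splits are too few for a share under 0.05. Every other split also mixes libraries of both groups, which widens the spread where genes truly differ. The counts of 0 therefore do not measure how many calls chance alone would give. For the difference of ligand responses, 1 of 100 regroupings, the real one, gave 2 calls and the highest other gave 1, but these are the regroupings that mix treated with untreated libraries, so they leave chance open for that count.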
